A study of Homo sapiens with 4 samples.

How the data were processed

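RNA of SUM159 cells with an inducible miR-100 construct was hybridised to Affymetrix whole-genome expression arrays, 1 array for each of 4 groups: ALDH-positive control, ALDH-positive DOX, ALDH-negative control and ALDH-negative DOX. The deposited values are log2 probe set summaries, which per the labels the authors made with RMA, a method that corrects background, normalises quantiles between arrays and summarises probes. Its version is not given in the sources used here. The 4 arrays had medians of 6.21, 6.22, 6.18 and 6.19 and nearly equal quartiles. The deposited values were used without further scaling. The number of arrays limits the precision, and p-values measure the spread between these arrays, which may be technical.

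Of 54675 probe sets, 62 were controls. An array annotation dated 2016 gave 41097 probe sets 1 gene, 1801 several genes and 11777 none. Symbols were updated by gene identifier. Among probe sets annotated to a gene alone, the one with the highest mean over the 4 arrays stood for the gene, which left 19775 genes, of which 12365 reached a log2 level of 6 in at least 1 array.

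For each pair of arrays the difference of log2 values was called at 2-fold or more (an absolute difference of 1) with a level of 6 in at least 1 of the 2 arrays. Such calls rest on size and carry no p-value, since each group held 1 array. A difference from a level under 6 is a difference from background, so that its size is uncertain, and the value with levels under 6 set to 6 is given where it moved. The difference between the DOX differences of the fractions was called in the same way. An additive model with terms for ALDH fraction and DOX was fitted to all 4 arrays with limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3. It left 1 residual degree of freedom and a prior of 11.6 degrees of freedom, and it counts any difference in response between fractions as error. P-values were two-sided and adjusted by Benjamini and Hochberg over the 12365 genes and, for a fixed list, over the list alone. Agreement between pairs was described by correlations across genes and by shared calls against n1 x n2 / N.

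The 34 gene lists, the rule for naming genes, the thresholds and the alternatives were fixed before the data were examined, with 1 exception, the target list without 3 members. A list was described by its median difference over members at a level of 6 in at least 1 array, and by the percentile of that median among 10000 random lists of the same size drawn from the same 20 bins of mean level. The percentile describes these arrays and is not a test of the conditions. Lists with fewer than 3 measured members got no percentile. Genes named are the 10 largest differences each way in the DOX comparisons of each fraction and the ALDH comparison of the controls, and the 5 largest in the others. Their probe sets at the level of 6 had to go the same way. For the additive model the 5 largest that passed were named, or the 3 of smallest p where none passed. Up to 4 members per list, all reported miR-99/100 targets and all ALDH genes were eligible too. Pseudogenes and unnamed loci were passed over.

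Alternatives were centring of each array on its median, cyclic loess, no filter on level, a level of 7, values under 6 set to 6, the mean of a gene's probe sets, leaving out probe sets of the shared kinds (names ending in _x_at or _s_at), a size of 1.5-fold, eBayes without trend or with robust estimation, and random lists not matched on level. Where the probe set left for a gene lay under a level of 6, its value is a difference of background and gives no direction. The steps were tested on simulated data with the spread of the ALDH-positive pair. Of genes simulated at a log2 difference of 1.5, 85% were called by size and 93% passed the additive model, against 2.17% and 0.0865% of unchanged genes. The simulation gave both DOX arrays the same difference and all levels the same spread, as the additive model assumes. These rates do not carry over to genes whose response differs between fractions. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.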

Results

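Gene expression was measured in SUM159, an established human breast cancer cell line of mesenchymal, hormone receptor-negative character. The cells carried a doxycycline-inducible construct for the microRNA miR-100. They were sorted by flow cytometry on aldehyde dehydrogenase (ALDH) status, a marker used to enrich breast cancer stem-like cells. Both fractions were then cultured in suspension with or without doxycycline (DOX). The labels give 10 h of doxycycline in the sample titles and the treatment protocol, but 13 h and doxorubicin, another drug, in the sample descriptions. The word DOX is used here for the treated samples, and doxycycline is taken from the titles. The series' design text states the aim as finding what miR-100 acts on in cells with and without stem-like properties. There were 4 groups with 1 array each, so that no difference between 2 arrays has a replicate check or a p-value. Of 19775 genes with a probe set of their own, 11799 reached a log2 level of 6 in the ALDH-positive control array, 11935 in ALDH-positive DOX, 11601 in ALDH-negative control and 11664 in ALDH-negative DOX. The number of arrays limits the precision of every value. The mature miR-100 is not measured by these arrays, so that its induction was not checked here, and cells without the construct that received doxycycline were not analysed here.

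The ALDH-positive and ALDH-negative fractions of the control cells differed in single genes such as MMP1 and INHBE and in lists such as ATF4 and G1/S genes. MMP1, the interstitial collagenase, had a log2 level of 4.21 in ALDH-positive and 10.13 in ALDH-negative cells, a difference of -5.92. MMP3, another matrix protease, differed by -3.60, the endothelial adhesion molecule PECAM1 by -3.80, the lysophospholipid receptor S1PR3 by -3.69 and SHISA2 by -4.29. P2RY8 (-3.87), COL3A1 (-3.87), CHRNA9 (-3.69), AQP9 (-3.65) and the prostaglandin-degrading enzyme HPGD (-3.57) completed the 10 lowest. In the other direction INHBE, which encodes an activin subunit, was higher by 4.82 in ALDH-positive cells (log2 10.40 against 5.58), and CHAC1, a glutathione-degrading enzyme induced by ATF4, by 4.50. ECM2 (4.01), ANXA3 (3.94), the tight junction protein CLDN1 (3.93), MYOZ2 (3.83), LINC01133 (3.80), MKX (3.73), NEURL1B (3.68) and RSAD2 (3.62) followed on the log2 scale. By the size rule of 2-fold with a level of 6 or more in at least 1 array, 734 genes were higher and 530 lower in ALDH-positive cells, of 12052 compared. Of the 552 called genes with 2 or more probe sets at that level, 500 had all of them on the same side. Without the probe sets that can hybridise to several transcripts, named shared probe sets from here on, MYOZ2 was at 1.18 and COL3A1 at -0.35. With levels under 6 set to 6, the background of these arrays, MMP1 was at -4.13, SHISA2 at -3.05, S1PR3 at -2.26, CHRNA9 at -2.24, MMP3 at -1.89, NEURL1B at 2.85, ANXA3 at 2.84, LINC01133 at 2.22, RSAD2 at 1.94 and MKX at 1.15.

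The ALDH genes themselves divided. ALDH1A1, an enzyme linked to the activity that the sort selects for, was at 11.77 in ALDH-positive and 10.72 in ALDH-negative control cells, a difference of 1.05. ALDH6A1 (1.93) and ALDH3B1 (1.63) also passed 2-fold, while ALDH1A3 differed by 0.63, ALDH3A2 by -0.57 and ALDH5A1 by -0.95. ALDH6A1 was at 0.95 without shared probe sets. Over the 14 measured members of the 19 fixed ALDH genes the median difference was 0.07, at the 64.6th percentile of 10000 random lists matched on mean level.

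Genes of the integrated stress response, the amino acid and stress programme driven by ATF4, were higher together in ALDH-positive cells. Of 31 measured members, 30 lay above 0 and 18 were 2-fold or more higher, with a median of 1.41 that was above all 10000 random lists. CHAC1 (4.50), GDF15, PCK2 (2.79) and NUPR1 (2.65) differed the most, and GDF15 was at 1.26 without shared probe sets. Interferon-stimulated genes had a median of 0.52, also above all random lists, with 8 of 29 members 2-fold or more higher. They included RSAD2 (3.62), IFIT2 (3.13), IFIT1 (2.71, or 1.23 with levels under 6 set to 6) and HERC5 (2.62, or 1.60). Without shared probe sets the interferon list's median was 0.31, at the 97.1st percentile. Genes of NF-kB signalling and inflammation had a median of 0.37 (99.7th percentile), with IL1A at 2.70. IL1A was at -1.15 without shared probe sets, but from a probe set under a level of 6 in all arrays. Immediate early genes had a median of 0.22 (99.6th percentile).

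Replication genes were lower in ALDH-positive control cells. All 30 measured genes of the G1/S phase lay below 0, with a median of -1.05 that was below all 10000 random lists, and 18 were 2-fold or more lower. FEN1 (-2.06), CCNE2 (-1.90), MCM10 (-1.51) and CDT1 were the furthest. Genes of the G2/M phase had a median of -0.14, at the 8.63rd percentile, with 1 of 36 members 2-fold lower. Cholesterol synthesis genes had a median of -0.86, below all random lists, with 21 of 22 below 0, among them HMGCS1 (-1.80), INSIG1 (-1.70), IDI1 (-1.63) and DHCR7 (-1.51). The value for IDI1 was 0.21 when shared probe sets were left out. Heat shock genes had a median of -0.50, below all random lists, led by HSPH1 at -1.20. Core histone genes had a median of -0.52 (0.17th percentile), drug and xenobiotic metabolism genes -0.27 (0.33rd), glycolysis genes -0.27 (0.33rd) and mitochondrial ribosome genes -0.23 (1.12th).

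Luminal and basal breast genes were both higher in ALDH-positive cells, and mesenchymal genes went both ways. Luminal breast genes had a median of 0.71 (99.9th percentile of random lists, 6 of 17 members measured), with GATA3, a luminal transcription factor, at 2.32 and KRT7 at 1.36. Basal breast genes had a median of 0.62 (99.8th percentile, 9 of 18 measured), with ITGB4 at 2.26 (0.72 without shared probe sets) and KRT5 at 1.02 but SFN at -1.51. Mesenchymal genes had a median of 0.00 (55.6th percentile), with COL3A1 at -3.87, PRRX1 at -2.40 and S100A4 at -1.67. Epithelial genes had a median of 0.19 (76.3rd percentile), with ESRP1, a splicing regulator, at 3.09. Breast stem-like cell genes had a median of -0.03 (38.8th percentile), with ABCG2 at -1.30, PROM1 at 1.21, KLF4 at 1.12 and SOX9 at -1.05. Among markers of other cell types, 4 of 22 immune genes were measured and all 4 lay above 0, LAPTM5 at 1.76 and CD74 at 1.09. HLA-DRA and MS4A1 among them reached a level of 6 only in ALDH-positive arrays, which favours values above 0. Endothelial markers went apart, with KDR at 3.08 and PECAM1 at -3.80, and HBB, 1 of 2 measured erythroid and platelet markers, was at 1.21 and at 0.18 without shared probe sets. With levels under 6 set to 6, KDR was at 2.21, PRRX1 at -1.09, ESRP1 at 0.99 and PROM1 at 0.00. Among the other lists cytosolic ribosomal protein genes had a median of 0.07 (97.9th percentile). Unfolded protein response genes had a median of 0.12 (95.8th percentile), hypoxia genes 0.14 (96.8th), apoptosis regulators 0.19 (95.5th), Notch and Hedgehog genes 0.15 (89.1st), BMP and TGF-beta signalling genes 0.10 (83.8th), p53 targets 0.09 (82.4th), Wnt pathway genes 0.04 (58.9th), SWI/SNF and ISWI remodellers -0.02 (56.3rd), mTOR pathway genes -0.10 (15.7th), respiratory chain genes -0.10 (5.94th) and housekeeping genes -0.06 (28.2nd).

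**Figure D1:**
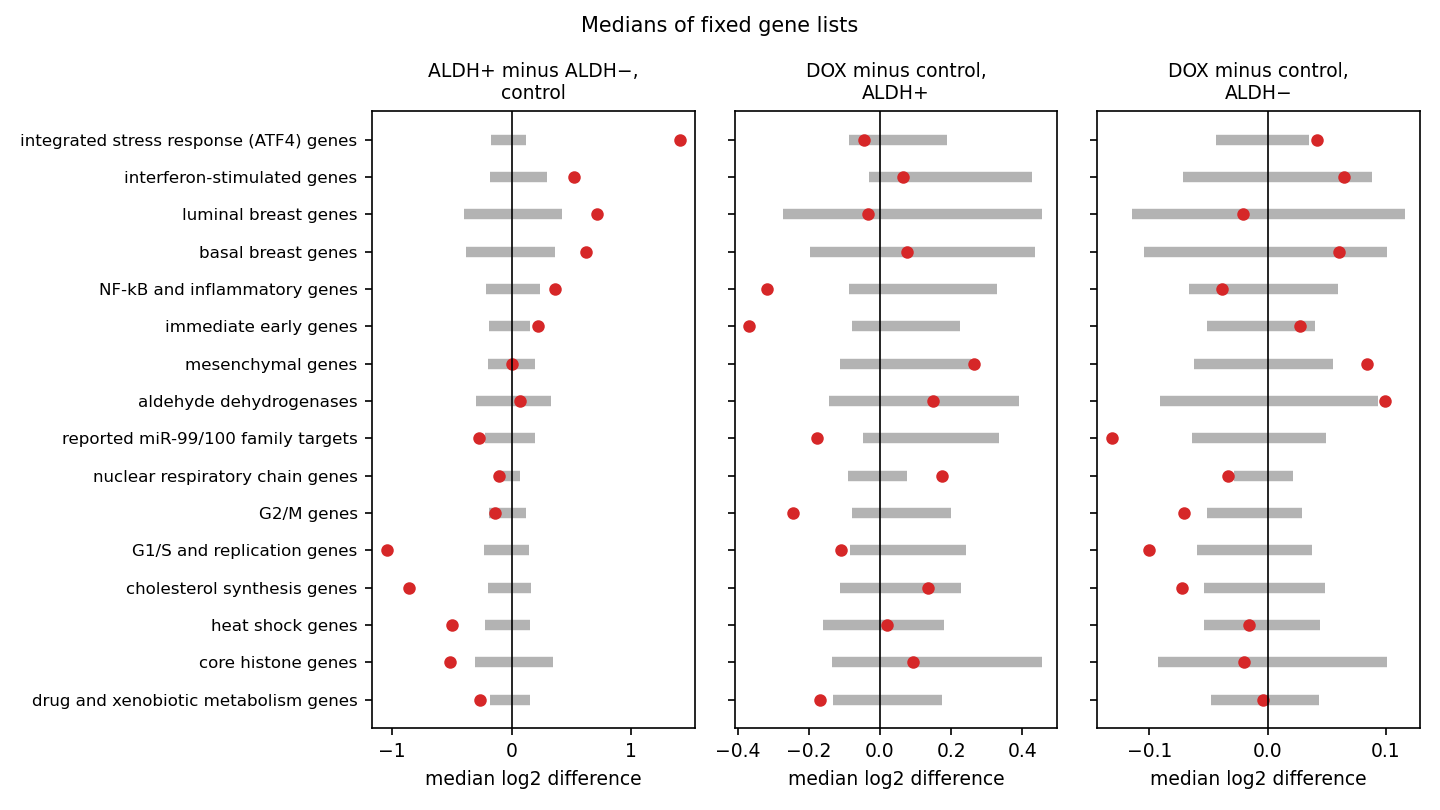
Median log2 differences of 16 of the fixed gene lists (red points) in 3 comparisons of 1 array against 1, with the central 95% of medians of 10000 random lists of the same size and mean level (grey bars). Each panel has its own horizontal scale. In the left panel ATF4 genes lie at 1.41 and G1/S genes at -1.05; in the right panel the reported miR-99/100 targets lie at -0.13.

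The ALDH comparison was repeated in the DOX-treated arrays, which share no array with the control comparison. Across 11915 genes the differences correlated with Pearson's r = 0.757 and Spearman's rho = 0.692, where genes are not independent replicates. Of the called genes, 574 were higher in both comparisons, against 76.5 for independent lists, and 263 were lower in both, against 27.7. The DOX comparison alone called 1396 genes higher and 650 lower of 12228, and 1133 and 842 after each array was centred on its median. Its leading genes were INHBE (5.09), MYOZ2 (4.76), CHAC1 (4.22), VSIR (4.11) and LINC01133 (3.97), and on the other side MMP1 (-5.77), IL33 (-4.75), POSTN (-4.37), IGF2BP3 (-4.29) and LIPG (-4.29). IGF2BP3 was at 0.14, MYOZ2 at 1.64 and POSTN at -2.73 without shared probe sets. The probe set left for IGF2BP3 lay under a level of 6 in these arrays. With levels under 6 set to 6, MMP1 was at -4.20, IL33 at -3.71, POSTN at -2.65, LIPG at -2.24, INHBE at 4.37 and LINC01133 at 2.87. Among lists, ATF4 genes had a median of 1.02, interferon-stimulated genes 0.62, G1/S genes -1.10, cholesterol synthesis genes -0.57, heat shock genes -0.40 and drug and xenobiotic metabolism genes -0.57. NF-kB genes, above 0 in the control comparison, had a median of -0.27 (0.52nd percentile). G2/M genes were at -0.38, below all random lists, and Wnt pathway genes at -0.23 (0.86th percentile). Without shared probe sets the NF-kB and Wnt medians were each 0.05. ALDH1A1 was not higher in ALDH-positive cells here, at 10.66 against 10.86, and ALDH1A3 was at 6.64 against 7.79.

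An additive limma model over all 4 arrays, in which each treatment served as the repeat of the other, tested the mean ALDH difference. It had 1 residual degree of freedom per gene before moderation, and its p-values measure the spread between arrays that may come from 1 sort. At a Benjamini-Hochberg adjusted p under 0.05, 1672 genes were higher and 1184 lower in ALDH-positive cells, of 12365 tested. Without the trend of the variance on the level, these counts were 998 and 529, and without a filter on level 767 and 410. INHBE was higher by 4.95 ± 0.28 (SE, limma adjusted p = 1.35e-06) and MMP1 was lower, with -5.84 ± 0.28 (limma adjusted p = 4.05e-07), each in the same direction in both pairs. Of the 31 ATF4 genes, 23 rose and none fell, also when adjusted over the list alone. Of 30 G1/S genes 26 fell, or 28 when adjusted over the list alone, and of 22 cholesterol genes 15 fell, or 16 when adjusted over the list alone. Among interferon-stimulated genes 9 rose and 3 fell (13 and 4 when adjusted over the list alone). Among ALDH genes ALDH6A1 and ALDH3B1 (1.91 ± 0.26 SE) rose and ALDH3A2 (-0.80 ± 0.17 SE) fell, the same 3 when adjusted over the list alone. ALDH6A1 was at 0.95 in the control and 0.17 in the DOX arrays without shared probe sets.

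DOX treatment of ALDH-positive cells went with differences in single genes such as MEX3D and HNRNPL and in lists such as NF-kB and immediate early genes. COL3A1, a fibrillar collagen, was at 5.76 in the control and 11.24 in the DOX array, a difference of 5.48, on all 3 of its probe sets that reached a level of 6. The sodium channel SCN1A (2.54), SNED1 (2.47), the netrin receptor UNC5C (2.46), the basement membrane protein NID2 (2.43), histone H3C6 (2.37), ALPK2 (2.28), PCDH18 (2.23), VIPR1 (2.22) and the cadherin CDH6 (2.19) were the next highest. MEX3D, an RNA-binding protein, was lower by -4.80 (10.77 to 5.97), the splicing factor HNRNPL by -3.71 and the matrix glycoprotein THBS1 by -3.54 on all 7 of its probe sets at that level. HMOX1, the haem-degrading enzyme, differed by -2.91, GPR180 by -2.87, ZNF532 by -2.85, MTA2 by -2.69, the kinase SIK1 by -2.59, the chemokine CCL20 by -2.54 and SNRNP40 by -2.54. By size, 422 genes were higher and 280 lower, of 12151 compared. Without shared probe sets COL3A1 was at 0.59, THBS1 at -1.22, ZNF532 at -0.09 and SIK1 at -0.32. With levels under 6 set to 6, SCN1A was at 0.24, NID2 at 1.63 and MTA2 at -0.86.

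The median of all genes in this pair lay at 0.12, and centring each array on its median gave 265 higher and 387 lower. The mean of a gene's probe sets gave 248 higher and 246 lower. Of 286 called genes with 2 or more probe sets at the level of 6, 211 had all on one side. Among control probe sets the bacterial ones had a median difference of -0.06. Their highest level in any array was 4.93, so that this is a difference of background and no check of hybridisation. The 3' and 5' probe sets of 18S ribosomal RNA were lower than in the ALDH-positive control by -1.90 and -1.94, against 0.45 and 0.20 in the ALDH-negative pair, while its middle probe set was at -0.30, against 0.07. The 3' probe set also differed by 1.06 in the ALDH comparison of the control arrays. The differences of a gene's 2 brightest probe sets correlated with r = 0.467 across 4565 genes in this pair, against 0.511 in the ALDH-negative pair, 0.791 in the ALDH comparison of the control arrays and 0.677 in that of the DOX arrays, where genes are not independent replicates.

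Among the fixed lists in the ALDH-positive pair, inflammatory and early response genes were lower. NF-kB genes had a median of -0.32, below all 10000 random lists, with 6 of 23 members 2-fold or more lower, among them CCL20 (-2.54), IL1A (-2.30), CXCL8 (-2.09) and IL6 (-1.98). IL1A was at -0.23 without shared probe sets, from a probe set under a level of 6. Immediate early genes had a median of -0.37, also below all random lists, with EGR3 (-1.72, or -0.89 with levels under 6 set to 6), ATF3 (-1.70), CCN2 (-1.62) and SPRY2 (-1.16). Drug and xenobiotic metabolism genes had a median of -0.17 (0.73rd percentile), with HMOX1 and GCLC (-1.21, or -0.32 without shared probe sets) in front. G2/M genes had a median of -0.24 (0.01st percentile), with 32 of 36 below 0, and G1/S genes -0.11 (1.33rd percentile). KIF23, the furthest G2/M gene at -1.70, was at 0.33 without shared probe sets. Nuclear genes of the respiratory chain lay above 0 for 37 of 40, with a median of 0.17 that was above all random lists, and none reached 2-fold. Glycolysis genes had a median of 0.18 (98.7th percentile). Mesenchymal genes had a median of 0.26 (98.0th percentile), with 7 of 23 members 2-fold or more higher, COL3A1, COL5A1 (1.78), FBN1 (1.69) and PRRX1 (1.29, or 0.00 with levels under 6 set to 6) in front, and FBN1 at 0.83 without shared probe sets. ALDH1A1 was lower by -1.11 (11.77 to 10.66), ALDH8A1 was at 1.54 and ALDH7A1 at 1.05.

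Other lists in the ALDH-positive pair lay nearer to the random lists. The mTOR pathway genes had a median of 0.31 (95.5th percentile), with TSC2 at 1.56 and ULK1 at 1.03, and TSC2 at -0.13 without shared probe sets. SWI/SNF and ISWI chromatin remodellers had a median of -0.04 (14.0th percentile), with ARID1B at -1.67. BMP and TGF-beta signalling genes had a median of -0.03 (7.88th percentile), with TGFB1 at 1.37 and ACVR1 at -1.15. TGFB1 was at -0.16 without shared probe sets, from a probe set under a level of 6. Wnt pathway genes had a median of 0.07 (20.4th percentile), Notch and Hedgehog genes -0.04 (10.2nd), p53 target genes -0.02 (7.37th), apoptosis regulators 0.04 (24.9th), hypoxia genes -0.00 (23.1st) and breast stem-like cell genes 0.07 (50.2nd). Of the 4 measured immune markers, MS4A1 (1.73, or 0.21 with levels under 6 set to 6) and CD74 (1.33) were 2-fold or more higher.

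DOX treatment of ALDH-negative cells left the array close to its control, with a correlation of 0.996 over all probe sets, and a small set of genes stood out. POSTN, the matrix protein periostin, was at 5.20 in the control and 8.65 with DOX, a difference of 3.45. The collagen COL1A2 (4.48 to 7.91) and ATP6V0D2, a subunit of the vacuolar proton pump (3.79 to 7.14), differed by 3.44 and 3.35. NID2 (2.92), UCHL1 (2.81), the prostacyclin synthase PTGIS (2.41), the cytokine IL33 (2.14), the natriuretic peptide NPPB (2.06), NPAS3 (2.01) and ALDH1A3 (1.94) followed. Without shared probe sets UCHL1 was at -0.03, COL1A2 at 0.06 and POSTN at 2.55. The probe sets left for UCHL1 and COL1A2 lay under a level of 6, so that their values are differences of background. TF, transferrin, was lower by -1.37, SCNN1G by -1.27, the chemokine receptor CXCR4 by -1.25, NELL2 by -1.19, LAMP3 by -1.15 and the interferon-induced chemokine CXCL10 by -1.03. TF was at -0.18 without shared probe sets. With levels under 6 set to 6, 22 genes were higher and 2 lower, with POSTN at 2.65, COL1A2 at 1.91, ALDH1A3 at 1.79, ATP6V0D2 at 1.14, NPPB at 0.93, UCHL1 at 0.89, PTGIS at 0.62, TF at -0.82, LAMP3 at -0.32, NELL2 at -0.28 and CXCL10 at -0.23.

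In all, 32 genes were higher and 6 lower by 2-fold in the ALDH-negative pair, of 11819 compared, and all 12 called genes with several probe sets had them on one side. Using the mean of a gene's probe sets, 18 were higher and 3 lower. The robust SD of the differences over genes was 0.13, against 0.43 in the ALDH-positive pair. Mesenchymal genes had a median of 0.08 (99.8th percentile of random lists), with 19 of 23 above 0 and 2 called, POSTN and COL1A2; ACTA2 was at 0.87 and COL1A1 at 0.50. ALDH genes had a median of 0.10 (98.0th percentile), led by ALDH1A3. G1/S genes had a median of -0.10 (0.01st percentile, 23 of 30 below 0) and G2/M genes -0.07 (0.20th percentile, 30 of 36 below 0). Cholesterol synthesis genes were at -0.07 (0.43rd percentile), Notch and Hedgehog genes at -0.11 (0.32nd) and respiratory chain genes at -0.03 (0.97th). Hypoxia genes (0.06, 99.8th percentile), epithelial genes (0.17, 99.1st), ATF4 genes (0.04, 99.1st), mTOR pathway genes (0.07, 98.8th) and p53 targets (0.05, 98.2nd) lay on the other side. The mTOR list had a median of -0.01 with the mean of each gene's probe sets. NF-kB genes had a median of -0.04 (13.4th percentile), with the chemokine CCL2 at 1.90 (1.23 with levels under 6 set to 6).

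**Figure D2:**
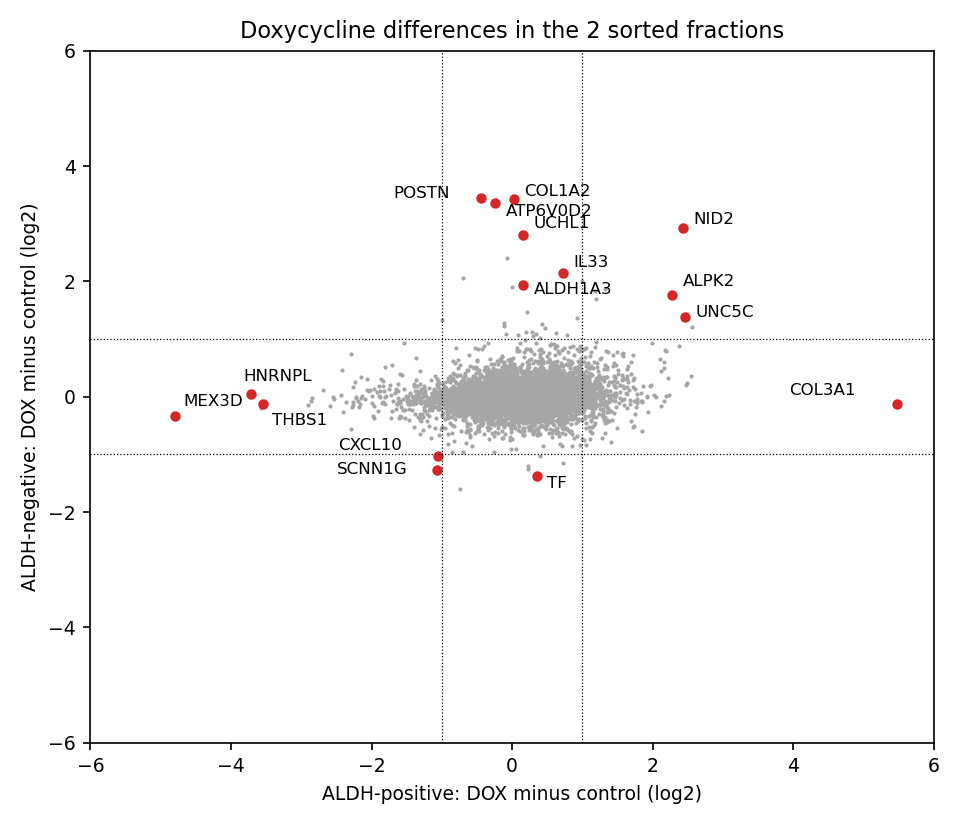
Log2 difference with DOX in ALDH-positive cells (horizontal) against that in ALDH-negative cells (vertical), 1 array against 1 each. Grey points are genes at a level of 6 or more in at least 1 of 4 arrays, red points are named genes and dotted lines mark 2-fold; COL3A1 lies at 5.48 and -0.12, POSTN at -0.44 and 3.45, NID2 at 2.43 and 2.92.

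The DOX differences of the fractions, which share no array, correlated weakly over all genes and overlapped more among called genes. Across 11605 genes Pearson's r was 0.139 and Spearman's rho 0.110, where genes are not independent replicates. ALPK2, NID2, SAMD9L, TES, TTC39B and UNC5C were 2-fold or more higher in both, 6 genes against 0.534 for independent lists. CXCL10 and SCNN1G were lower in both, 2 genes against 0.136. No gene was called in opposite directions, but with 19 higher and 6 lower genes of the ALDH-negative pair compared, few such calls were possible. Of these 25 genes, 19 had the same sign in the ALDH-positive pair. Genes under a level of 6 in both ALDH-positive arrays, POSTN, COL1A2 and ATP6V0D2 among them, were left out of this comparison. The difference between the DOX differences was 2-fold or more for 765 genes, 468 higher and 297 lower in ALDH-positive cells, and 297 and 439 after centring, none of it tested. COL3A1 (5.60), CSMD3 (2.27), SNED1 (2.27), S100A8 (2.25) and ATXN7L3-AS1 (2.23) led on one side, and MEX3D (-4.47), POSTN (-3.89), HNRNPL (-3.77), ATP6V0D2 (-3.59) and COL1A2 (-3.41) on the other. Without shared probe sets COL1A2 was at 0.04, COL3A1 at 0.56 and S100A8 at 1.41. The probe set left for COL1A2 lay under a level of 6. With levels under 6 set to 6, POSTN was at -2.65, COL1A2 at -1.91, ATP6V0D2 at -1.14, ATXN7L3-AS1 at 1.53, S100A8 at 0.54 and CSMD3 at 0.26.

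In the additive limma model NID2 was the 1 gene that passed for the mean DOX difference, higher by 2.67 ± 0.29 (SE, limma adjusted p = 0.00620) and in 2 of 2 pairs. None was lower, while at an unadjusted p under 0.05 there were 368 higher and 284 lower. The count was 0 with centring, cyclic loess, no filter on level, values under 6 set to 6, or no trend, and 4 at a level of 7. The genes of smallest p on the lower side, SCNN1G (-1.17 ± 0.27 SE), PWAR5 (-1.43 ± 0.37 SE) and JCHAIN (-1.17 ± 0.31 SE), had limma adjusted p of 0.748, 0.806 and 0.806. Adjusted over the list alone, COL1A1 (0.81), ACTA2 (1.03), COL1A2 (1.73), COL3A1 (2.68) and FBN1 (1.04) rose among mesenchymal genes, and CXCL1 (-0.91), CXCL8 (-1.06), IL6 (-1.15) and PTGS2 (-0.97) fell among NF-kB genes, with none of these past the adjustment over all genes. COL3A1 lay at 5.48 in 1 pair and -0.12 in the other. COL1A2 lay at 3.44 in the ALDH-negative pair, and at levels of 4.54 and 4.56 in the ALDH-positive control and DOX arrays. Its value of 0.06 in the ALDH-negative pair without shared probe sets came from a probe set under a level of 6, a difference of background. CXCL8 also moved in 1 pair, from 11.94 to 9.85 in ALDH-positive cells, with levels of 11.93 and 11.89 in the ALDH-negative control and DOX arrays. MYC (-0.62) was the 1 breast stem-like gene to fall when adjusted over the list alone. It moved mostly in ALDH-positive cells, from 13.54 to 12.41, against 13.33 to 13.22 in ALDH-negative cells.

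Reported targets of the miR-99/100 family, the question of the series, were lower as a list in both DOX comparisons by small amounts. Of 37 fixed targets 29 were measured. In ALDH-negative cells 19 lay below 0, with a median of -0.13 that was below all 10000 random lists, whose median was -0.01. None reached 2-fold. FZD5 (-0.60), RRAGD (-0.59), HS3ST3B1 (-0.41), TRIB2 (-0.39) and CTDSPL (-0.32) were the furthest, and MTOR, the growth-regulating kinase, was at -0.23. FZD5 was at -0.08 without shared probe sets, from a probe set under the background level. Other fixed lists also lay near the ends of their random lists in the ALDH-negative pair, among them cholesterol synthesis, mesenchymal and hypoxia genes. An extreme percentile there is therefore not specific to the targets. In ALDH-positive cells 18 targets lay below 0, with a median of -0.18 (0.08th percentile), where the random lists had a median of 0.14. That median was -0.47 with the mean of each gene's probe sets. AP1AR was at -1.81, ID1 at -0.88, AGO2 at -0.78 and RRAGD at -0.73, while RPTOR was at 0.69, ZZEF1 at 0.61 and MTOR at 0.37. The chromatin remodeller SMARCA5 was at -0.23 in ALDH-positive and -0.09 in ALDH-negative cells, SMARCD1 at -0.63 and -0.26, and the receptor BMPR2 at 0.12 and 0.03. These 3 were put in the list from memory of a report on these cells, so that they are not independent evidence. Without them the medians were -0.16 and -0.14. No target passed the additive limma model for DOX, nor when adjusted over the list alone (smallest adjusted p = 0.183). The list was low in the ALDH comparison of the control arrays as well, with a median of -0.27 (0.95th percentile) and with TRIB2 (-1.65), RPTOR (-1.49), CCN1 (2.53) and ID1 (2.52) as its furthest members. That percentile was 6.76 without the 3 genes.

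**Figure D3:**
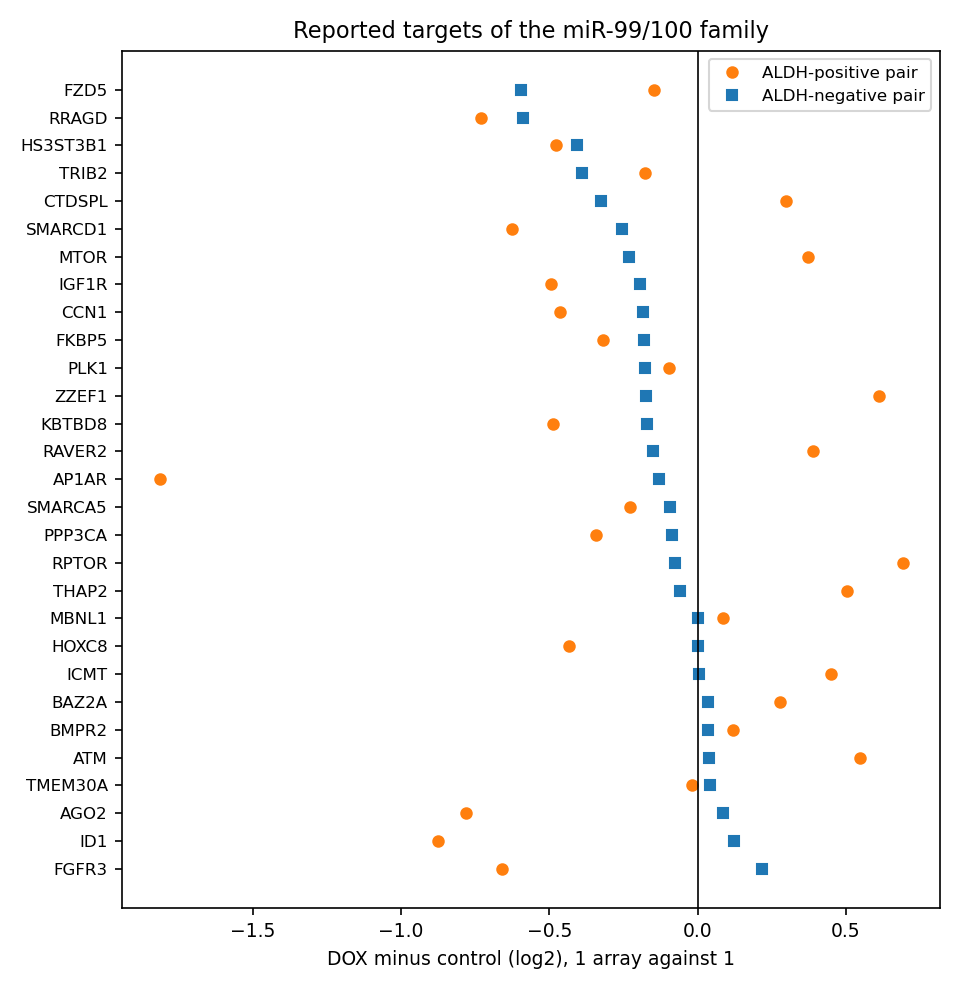
Log2 difference with DOX for the 29 measured reported targets of the miR-99/100 family in the ALDH-positive pair (circles) and the ALDH-negative pair (squares), 1 array against 1, ordered by the ALDH-negative difference. In the ALDH-negative pair 19 squares lie below 0, FZD5 furthest at -0.60; the circles spread from -1.81 for AP1AR to 0.69 for RPTOR.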

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

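All tests of explanations in this part were chosen only after the results were seen.

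In 4 genes the ALDH difference had opposite signs in control and DOX arrays, past 2-fold each time, and the change between them was not tested. COL3A1 was at -3.87 in the control comparison and 1.73 with DOX, a change of 5.60, and at 0.56 without shared probe sets. FTX was at -1.23 and 1.20 (2.43), ATXN7L3-AS1 at -1.09 and 1.14 (2.23, or 1.53 with levels under 6 set to 6) and JDP2 at 1.08 and -1.05 (-2.13).

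DOX went with 702 genes of 2-fold or more in ALDH-positive cells, against 38 in ALDH-negative cells. ALDH-negative cells mixed into the ALDH-positive DOX sample are argued against, since 6 of the 10 genes lowest in ALDH-positive control cells were higher by less than 0.5 or lower, and MMP1 lay at 4.43, against 10.13 in ALDH-negative control cells. The other 4 moved towards ALDH-negative cells, P2RY8 to a level of 8.37 (10.74 in ALDH-negative control cells), PECAM1 by 1.59, HPGD by 2.19 and COL3A1 by 5.48 (0.59 without shared probe sets), but a mixture would raise all 10. RNA quality or labelling of that array may account for part of the genes: the differences of a gene's 2 brightest probe sets correlated with r = 0.467 (bootstrap 0.435 to 0.501), against 0.791 (0.771 to 0.809) in the ALDH comparison of the control arrays and 0.677 in that of the DOX arrays, although the ALDH-negative pair, whose differences spread less, had 0.511 (0.453 to 0.562). A larger response of ALDH-positive cells stays open and cannot be told apart from this with 1 array per group, and the DOX differences of the fractions correlated with r = 0.139.

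The 38 genes of the ALDH-negative pair, POSTN and COL1A2 among them, are not a matter of more ALDH-positive cells alone, since 19 of the 32 higher genes lay 2-fold or more above both ALDH-positive arrays. Fewer ALDH-positive cells stay open for the lower genes: 14 of the 73 genes lower by 1.5-fold or more did not lie above the ALDH-negative DOX array in the ALDH-positive control array, and picking genes that are low in the former favours the other 59. Cells with a collagen-producing profile could have entered the sample: besides POSTN and COL1A2, 3 of 4 mesenchymal genes under a level of 9 in the ALDH-positive control array lay above 0, too few to decide, and COL3A1, abundant in such cells, was at -0.12. A response to DOX, with 6 genes called higher in both fractions, cannot be told apart from these with 1 array per group.

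The reported miR-99/100 targets lay low among random lists in both DOX comparisons. The low median in ALDH-negative cells does not rest on the members picked from a report on these cells, since without them it was -0.14. SMARCA5 and BMPR2 lay above the list median there, so that leaving these members out could not raise it. Whether the choice of the other members favoured a low median was not tested. Other fixed lists, such as hypoxia genes in ALDH-negative and NF-kB genes in ALDH-positive cells, also lay near the ends of their random lists. An extreme percentile is therefore not specific to the targets. A fall of miR-100 targets after induction may account for the low target medians, with 19 of 29 members below 0 in ALDH-negative cells. However, random lists were matched on level and not on the length of the untranslated region. A difference of the list that does not depend on DOX stays open: in the ALDH comparison of the control arrays the percentile was 0.95, and 6.76 at the highest among the settings tried. No cells without the construct were analysed here, so that effects of doxycycline itself were not separated.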

How the results depend on the processing

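Of the alternatives reported in this part, the target list without SMARCA5, SMARCD1 and BMPR2 was chosen only after the data were seen. Across settings, 1439 list medians stayed inside the central 95% of random lists or outside it on the same side. Another 96 moved inside it or to its other end, 36 moved outside it and 13 reversed. A list counted as reversed only if its median with the deposited values lay outside that range. Changes of sign within it were not counted. Of values of named genes 3753 stayed within the robust SD of their comparison, 400 moved further and 18 reversed. Only genes called 2-fold could count as reversed. Of counts and correlations 102 stayed and 28 moved. In the ALDH comparison of the controls the median ranged from 1.08 to 1.47 for ATF4 genes, -1.05 to -0.96 for G1/S genes and -0.93 to -0.73 for cholesterol genes, and for miR-99/100 targets in ALDH-negative cells from -0.16 to -0.09 and in ALDH-positive cells from -0.47 to -0.14. No analysis paired by replicate number was possible because the labels give none and each group holds 1 array, and the additive model pairs arrays by fraction and treatment only. The comparison of genes with miR-100 seed sites was not run, since no transcript sequences were available. Signal near background limits genes under a level of 6.

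Centring gave 265 genes higher with DOX in ALDH-positive cells, 297 higher for the difference of the DOX differences and 0 in the additive limma model for DOX. The mean of probe sets gave 248 and 270, and 18 higher and 3 lower in ALDH-negative cells. At 1.5-fold there were 1780 higher and 829 lower with DOX in ALDH-positive cells, 136 and 73 in ALDH-negative cells, 1664 and 1478 in the ALDH comparison of controls, 2805 and 1542 in that of DOX arrays, and 1827 and 927 for the difference of differences, because a lower threshold takes in more genes. A level of 7 gave 2 lower in ALDH-negative cells and 4 higher in the additive model for DOX; values under 6 set to 6 gave 2 and 0. The latter count was 0 also with cyclic loess, with no filter on level and with eBayes without trend. For ALDH the additive model gave 767 higher and 410 lower with no filter, and 998 and 529 without trend. The cause of these moves other than at 1.5-fold was not tested.

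Where a list median reversed or changed sides the cause was not tested. Centring gave -0.0162 for respiratory chain and -0.0441 for ribosomal genes in the ALDH comparison with DOX. No filter on level gave -0.0157 for basal and -0.0425 for immune genes there, and for immune genes -0.00784 with DOX in ALDH-positive cells and -0.0725 for the difference of differences. For the difference of differences the miR-99/100 list was at 0.0111 with a level of 7, at 0.0111 without shared probe sets and at 0.0111 without the 3 members. The mTOR list was at -0.00896 with DOX in ALDH-negative cells with the mean of probe sets. Without shared probe sets, p53 genes were at 0.0461 for the difference of differences, NF-kB and Wnt genes at 0.0487 and 0.0530 in the ALDH comparison with DOX, and interferon genes at 0.31 in that of controls.

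All genes counted as reversed did so without shared probe sets. Genes not called 2-fold could change sign without being counted. In the ALDH comparison with DOX, ICMT was at -0.60 and, without shared probe sets, at 2.67. For UCHL1, TGFB1, FZD5, IL1A, IGF2BP3 and COL1A2 the probe sets left lay under the background level, so that their values give no direction. The cause of the other reversals was not tested. With DOX in ALDH-positive cells TSC2 was at -0.13, TGFB1 at -0.16 and KIF23 at 0.33, and in ALDH-negative cells UCHL1 at -0.0274. In the ALDH comparison of controls FZD5 was at 0.16, ICMT at 1.23, IL1A at -1.15 and IDI1 at 0.21. In that with DOX IGF2BP3 was at 0.14, TSC2 at -0.75, TGFB1 at -0.48, COL1A2 at 0.0784 and ERG at 0.0134. For the difference of differences COL1A2 was at 0.0395, TSC2 at -0.40, TGFB1 at -0.80, KIF23 at 0.0756 and IL1A at 0.89.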

Other observations

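The genes in this part were chosen after their values were seen, and no explanation was tested.

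Single genes known from class II antigen presentation and B cells were higher in ALDH-positive cells. No list of such genes was fixed. In the fixed list of immune cell markers all 4 measured members, CD74, HLA-DRA, MS4A1 and LAPTM5, were higher, also when adjusted over the list alone. HLA-DRA and MS4A1 reached a level of 6 only in ALDH-positive arrays, so that the filter favoured this direction. Of the 19 members with a probe set of their own, 15 lay under 6 in all arrays. With no filter on level the list median was -0.04 (46.5th percentile) in the ALDH comparison with DOX. In the additive limma model HLA-DPA1 differed by 2.92 (adjusted p = 0.000218), POU2AF1, a B-cell coactivator, by 2.86 (0.000248), the immunoglobulin light chain IGLC1 by 2.81 (0.000345) and the invariant chain CD74 by 1.82 (0.00276), each higher in 2 of 2 pairs. HLA-DQA1 (2.37, adjusted p = 0.000348), JCHAIN (2.30, 0.000274), HLA-DRA (1.39, 0.00544), MS4A1 (1.35, 0.0354) and HLA-DMA (1.26, 0.0316) were higher as well. With levels under 6 set to 6, HLA-DRA differed by 0.02 in the control and 0.43 in the DOX arrays, and MS4A1 by 0.21 in the DOX arrays. MS4A1 passed 6 in the ALDH-positive DOX array alone. HLA-DPA1, POU2AF1, HLA-DQA1, JCHAIN and HLA-DMA also lay under 6 in ALDH-negative cells, so that the sizes of their differences are uncertain. They too passed the filter through ALDH-positive arrays alone, which favoured a higher value there. The values of IGLC1, HLA-DRA and HLA-DMA come from shared probe sets. In the order ALDH-positive control, ALDH-positive DOX, ALDH-negative control and ALDH-negative DOX, HLA-DPA1 lay at 6.90, 7.93, 4.87 and 4.12, and POU2AF1 at 6.69, 7.83, 4.71 and 4.08. IGLC1 lay at 9.01, 10.29, 7.20 and 6.49. Other genes stayed under a level of 6 in all arrays and were not tested. The B-cell receptor gene CD79A lay at 5.80, 5.66, 5.59 and 5.70. The leukocyte marker PTPRC lay at 4.93, 5.18, 4.19 and 4.22, and CIITA, the class II transactivator, at 4.54, 4.43, 4.58 and 4.54.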
